A study of Mus musculus with 15 samples.

How the data were processed

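The series holds 15 samples, of which 12 are RNA sequencing libraries of mouse prostate epithelial cells cultured as organoids. The other 3 are an H3K27me3 chromatin immunoprecipitation in each of 2 genotypes and an input, which were not analysed here. Per the labels, deletions were made in the prostate epithelium of C57BL/6 mice, total RNA was taken with TRIzol and sequenced as paired reads of 150 nucleotides on an Illumina HiSeq. The 6 RNA groups of 2 libraries each were control, Setd2 null, Ezh2 null and double null from 3-month-old mice, and wild-type Ezh2 and Ezh2 K735R from 2-month-old mice. In the first 4 groups each library came from an equal-mass pool of RNA of 3 biological replicates, per the labels. For the last 2 groups the labels refer to similar approaches and give no pool size.

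The deposited RPKM table of the first 4 groups lists 21886 genes, and the deposited count table of the last 2 groups lists 14301, all of which are also in the first table. Per the submitters' processing notes, reads were aligned to mm10 and the notes name Bowtie, RSEM, BWA and SICER for the series and Bowtie and RSEM for the K735R samples. Versions, strandedness and the way reads shared between genes were divided are not given in the sources used here. The deposited counts are whole numbers, and their unit was taken from the values. Spreadsheet software had turned 27 and 19 gene symbols into date numbers, and these were named from their Entrez identifiers. Entrez identifiers matched the reference table for 21653 and 14196 genes. At 0 in every library are 4001 genes of the RPKM values and 21 of the counts.

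Each gene's values in the deposited RPKM table were whole multiples of the value of 1 read, which gave the library totals and the reads per gene. Of 13748 genes above 0 in all 8 libraries, 13746 (99.99%) came out whole within 0.01 reads in every library. Recovered reads on listed genes ranged from 29692426 to 54211543 per library, which is 97.3% to 98.8% of the library totals, and 15041 to 16382 genes were above 0. Count totals ranged from 28831228 to 37482322.

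For the first 4 groups, values were transformed to log2(RPKM + 1), genes with a mean of at least 1 RPKM over the 8 libraries were kept (11338), and all 4 groups entered 1 linear model in limma 3.58.1 with trended, robust variance moderation. The contrasts were Setd2 null against control, Ezh2 null against control, double null against each single deletion and against control, and the interaction of both deletions. For the count table, edgeR 4.0.16 was run with TMM scaling, its filter on low counts (13203 genes kept) and the robust quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg method within each contrast and called at 0.05, two-sided. Fold changes compare group means on the fitted log2 scale, and a gene's level is the mean ± SD of RPKM, or of CPM from TMM-scaled library sizes. Chromosome positions are those of mm10.

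A total of 27 gene lists were fixed before the data were examined, as were the designs, the contrasts, the alternatives not said to be added later and the rule for named genes. They cover PRC2 subunits, other H3K36 and H3K27 methyl enzymes, Hox cluster genes, Polycomb-repressed developmental and cell cycle inhibitor genes, luminal, basal, neuroendocrine, seminal vesicle and urothelial epithelium, stroma, immune cells, endothelium, mesenchymal transition and epithelial junctions. They further cover proliferation, androgen response, glycolysis, AMPK and FOXO genes, the PI3K-AKT pathway, sterol and fatty acid synthesis, interferon response, MHC class I presentation, inflammatory cytokines and acute phase, matrix and adhesion receptors, Wnt feedback and receptors, immediate early and heat shock genes, replication-dependent histones and imprinted genes. The MHC list also holds some class II genes. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

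The rule named Setd2 and Ezh2 first, then the 10 highest and 10 lowest log2 fold changes (5 each for double null against Ezh2 null or control and for the interaction) among called genes whose libraries did not overlap and that reached 5 RPKM or CPM in the higher group. Predicted genes, clone names, pseudogenes and microRNAs were left out. It also named up to 4 members of each list by the smallest p, and 5 genes by the smallest p where too few passed. Of the genes it names, the text gives some in full and summarises the rest as counts. Genes listed as examples of overlaps were chosen after their values were seen.

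The alternatives were quantile normalization and median-ratio scaling, no filter, a mean of at least 5 RPKM or 10 counts, a pseudocount of 0.1, DESeq2 1.42.0 and limma on log2 CPM for the counts, no TMM factors, only the groups compared, the replicate number as a block, an absolute log2 fold change of at least 1, Spearman correlation, and leaving out each library in turn. Added after seeing the data were edgeR on the recovered whole reads and edgeR with every library thinned to 29692426 reads. Where a library is left out, the lone library of its group is assumed to vary like those of the other groups. Not reported here are some genes that the rule named, a run of 1 list without 2 of its genes, and a further alteration that all 6 groups carried and that differed between the first 4 and the last 2.

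Each test was first tested on simulated data with genes changed 1.5-, 2- and 4-fold. For Setd2 null against control limma recovered 11.9%, 53.7% and 93.9% of them (11248 genes run), for Ezh2 null against control 9.0%, 61.2% and 89.4% (11084 genes), and for double null against Setd2 null 9.0%, 53.7% and 89.4% (11051 genes). For double null against Ezh2 null it recovered 10.4%, 68.7% and 86.4% (11228 genes), and for double null against control 10.4%, 67.2% and 95.5% (11092 genes). For the interaction it recovered 1.5%, 11.9% and 69.7% (11202 genes), and for K735R edgeR recovered 7.5%, 40.3% and 87.9% (12967 genes). Unchanged genes called in these 7 simulations numbered 8, 5, 6, 24, 9, 5 and 16, in the order given, which is 17.9% of the calls for double null against Ezh2 null and 15.1% for K735R. Calls in those 2 contrasts may thus include more false ones than the adjusted p states. In each simulation camera called the changed list and 0 of 15 unchanged lists. The simulated genes varied independently of each other and the lists were drawn at random. These runs therefore cannot tell whether camera's calls hold for lists whose genes vary together. Each simulation also changed only 67, 67 and 66 genes, by 1.5-, 2- and 4-fold. The real fits called 6416 of 11338 genes for Ezh2 null against control and 1 of 13203 for K735R. The recovered shares therefore need not hold for the real libraries. The calculations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.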

Results

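Gene expression was measured by RNA sequencing of prostate epithelial cells grown as organoids from mice with conditional deletions in the prostate epithelium. In 4 groups from 3-month-old mice, which shared their other alterations, the cells carried no further deletion (control), a deletion of Setd2, a deletion of Ezh2, or both (double null). In the other two groups, from 2-month-old mice that differed from the first 4 groups in other alterations as well as in age, the cells carried either wild-type Ezh2 or the Ezh2 form K735R, in which a lysine is replaced by arginine. Each group had 2 libraries. In the first 4 groups each library was made from pooled RNA of 3 biological replicates, so the p-values measure the spread between pools, not between animals. Reads on listed genes, recovered from the values, numbered 29692426 and 29791131 in control, 32192778 and 34868827 in Setd2 null, 54211543 and 46970193 in Ezh2 null, and 48323029 and 49898971 in double null. Count totals were 28831228 and 37482322 with wild-type Ezh2, and 30404095 and 29221905 with K735R. Values in the first 4 groups are RPKM (reads scaled by gene length and library size), and their fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Values of the other two groups are CPM (counts scaled by library size only).

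The targeted genes were examined first. Setd2 encodes the enzyme that adds the third methyl group to lysine 36 of histone H3, and Ezh2 the catalytic subunit of Polycomb repressive complex 2 (PRC2). Setd2 (Entrez 235626) lies on the plus strand of chromosome 9 from 110529296 to 110618633 in mm10. Its RPKM was 16.6 ± 0.614 (SD, n = 2) in control, 9.51 ± 1.07 in Setd2 null, 13.1 ± 2.13 in Ezh2 null and 8.26 ± 1.03 in double null. Its lower level in Setd2 null did not pass limma's test (log2 fold change −0.74 ± 0.148 SE, adjusted p = 0.0563, with 0.0437 to 0.368 over the alternatives). In Ezh2 null against control its log2 fold change of −0.32 did not pass (limma adjusted p = 0.0872, with 0.0167 to 0.448 over the alternatives). Setd2 fell in double null against control (log2 fold change −0.93, limma adjusted p = 0.000642). Its fall against Ezh2 null passed with all libraries (log2 fold change −0.60, limma adjusted p = 0.0425). That call was lost without Ezh2 null 1 (limma adjusted p = 0.282), double null 1 (0.0637) or double null 2 (0.28), within a range of 0.0324 to 0.282 over the alternatives.

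Ezh2 (Entrez 14056) lies on the minus strand of chromosome 6 from 47530274 to 47595340. Its RPKM was 20.1 ± 1.04 (SD, n = 2) in control, 22.5 ± 2.5 in Setd2 null, 12.7 ± 1.59 in Ezh2 null and 15.4 ± 1.7 in double null. Ezh2 fell in Ezh2 null against control (log2 fold change −0.63 ± 0.142 SE, limma adjusted p = 0.00414). In double null against control it did not pass (log2 fold change −0.37, limma adjusted p = 0.0514, with 0.0109 to 0.272 over the alternatives). Its fall in double null against Setd2 null (log2 fold change −0.52, limma adjusted p = 0.0121) was lost without Setd2 null 1 (0.0657) or double null 2 (0.0912), with 0.00239 to 0.0912 over the alternatives. With wild-type Ezh2 and K735R, Setd2 was at 134 ± 4.56 and 135 ± 1.99 CPM and Ezh2 at 48.8 ± 12.8 and 47.5 ± 0.821 CPM. The tables give 1 value per gene, so transcripts that lack the deleted exons are still counted.

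**Figure D1:**
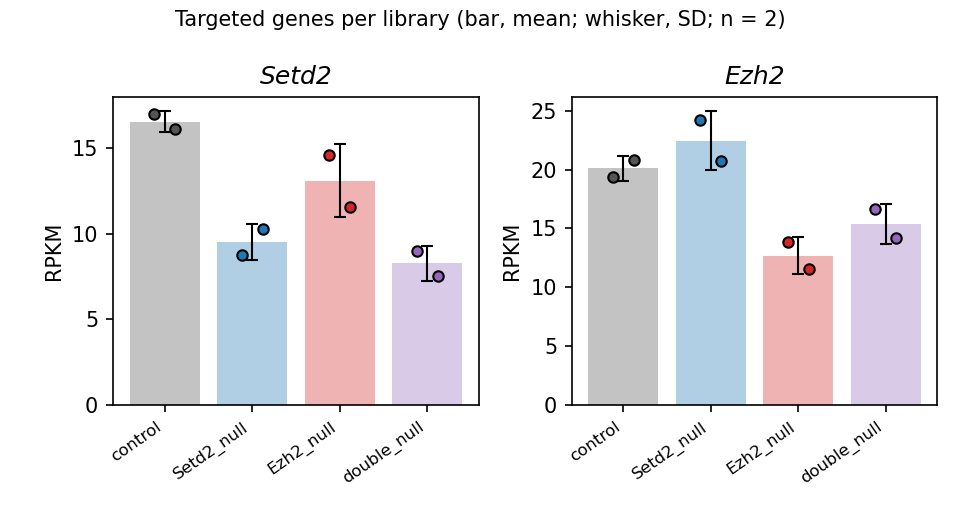
RPKM of Setd2 and Ezh2 in control, Setd2 null, Ezh2 null and double null libraries (points, libraries; bars, mean; whiskers, SD; n = 2). Setd2 was lowest in double null, at 8.26, and highest in control, at 16.6, while Ezh2 was lowest in Ezh2 null, at 12.7.

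The first principal component of log2(RPKM + 1) held 81.2% of the variance and separated the libraries by their Ezh2 genotype. Control and Setd2 null libraries scored from −54.49 to −48.31 on it and Ezh2 null and double null libraries from 45.51 to 54.4. The second component held 6.9% and separated the libraries numbered 1 from those numbered 2 within Ezh2 null (−20.99 and 20.63) and within double null (−19.62 and 21.29).

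**Figure D2:**
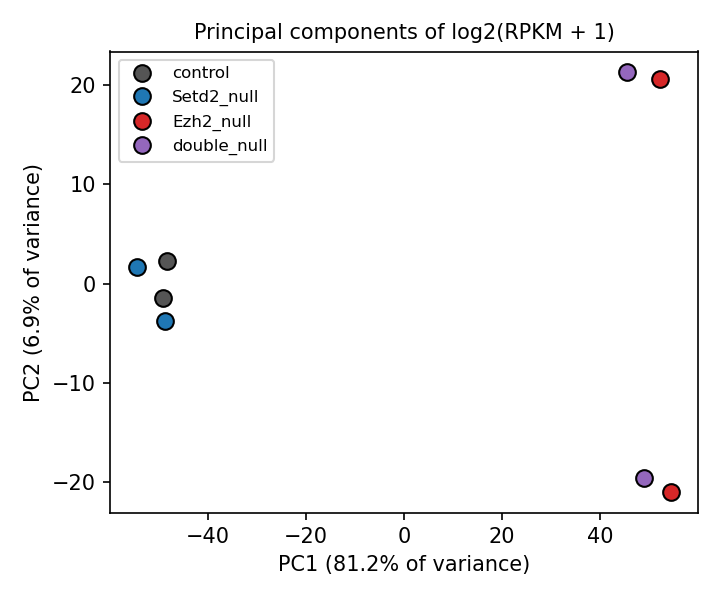
Scores of the 8 libraries on the first (x axis, 81.2% of variance) and second (y axis, 6.9%) principal components of log2(RPKM + 1). Each point is a library, coloured by group; the 4 libraries without Ezh2 score from 45.51 to 54.4 on the first component.

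The comparison of Setd2 null with control asks what loss of Setd2 does to expression while Ezh2 is intact. The surface glycoprotein gene Cd200 rose from 2.25 ± 1.75 to 49.1 ± 7.84 RPKM (SD, n = 2), a log2 fold change of 4.05 ± 0.333 SE (limma adjusted p = 0.00251). The interferon-inducible genes Ifi205 (11.1 ± 0.241 to 37.5 ± 0.0614 RPKM) and Mnda (8.05 ± 0.00839 to 22.4 ± 0.0168 RPKM) rose, as did the carbonic anhydrase gene Car12 (1.09 ± 0.0516 to 6.13 ± 0.777 RPKM) and the collagenase gene Mmp13 (26.6 ± 0.749 to 68.6 ± 0.476 RPKM). The ribosomal protein gene Rpl29 fell from 96.5 ± 10.02 to 12.7 ± 3.22 RPKM (log2 fold change −2.85 ± 0.168 SE, limma adjusted p = 0.000123). It has near-identical copies elsewhere in the genome (several pseudogenes), so its values are uncertain where the counting divided reads between copies. Lmcd1 fell from 5.98 ± 0.449 to 1.18 ± 0.15 RPKM, Ptprn from 11.02 ± 1.24 to 2.13 ± 0.785 RPKM and Wfdc18 from 9.9 ± 1.01 to 2.69 ± 0.419 RPKM.

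Of 11338 genes tested, limma called 121, with 43 higher and 78 lower (35.5% higher), against 1313 at an unadjusted p under 0.05. With the replicate number as a block it called 231, with 99 higher. Among the 121 genes of the main fit, 20 rose and 23 fell at least 2-fold. After quantile normalization the split was 25 higher and 31 lower (44.6% higher). The count fell to 25 without control 1, 24 without control 2 and 64 without Setd2 null 1. Calls on Cd200, Car12, Ifi205, Mnda, Mmp13 and Rpl29 held under each other setting run and without any single library. Those on the cornified envelope gene Ivl (log2 fold change 1.37) and the haptoglobin gene Hp (−1.51) were lost without control 1 (limma adjusted p = 0.163 and 0.0619) or control 2 (0.102 and 0.122), with 0.00872 to 0.163 and 0.0133 to 0.122 over the alternatives.

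Among the fixed lists, all 29 tested interferon response genes had positive log2 fold changes, with a median of 0.41 (camera adjusted p = 1.06e-10, and 0.709 with an estimated correlation). Over all genes tested and adjusted over the list alone, 2 of the 29 rose, Oasl1 (log2 fold change 1.22, limma adjusted p = 0.00424) and Rsad2 (0.86, adjusted p = 0.0248). Limma lost Oasl1 without control 1 (adjusted p = 0.0652), and Rsad2 without control 1 (0.128), control 2 (0.234), Setd2 null 1 (0.0743) or Setd2 null 2 (0.0824). Of 18 genes of MHC class I presentation 1 rose by either adjustment, H2-T22 (limma adjusted p = 0.0251, with 0.245 without control 1, 0.224 without control 2 and 0.059 without Setd2 null 2), and the list's median was 0.44 (camera adjusted p = 0.000175, and 0.709 with an estimated correlation). In the proliferation list 28 of 29 genes had positive log2 fold changes, including Mcm4 (0.46) and Cdc20 (0.47), but none passed by either adjustment (median 0.30, camera adjusted p = 1.44e-07, and 0.709 with an estimated correlation). Among 23 Polycomb-repressed developmental and cell cycle inhibitor genes 0 passed over all genes and 4 were lower adjusted over the list alone (median −0.26, camera adjusted p = 0.000315, and 0.709 with an estimated correlation). Timp3 and Dkk3 were among them. The lists of AMPK and FOXO genes (21 tested, 0 over all genes and 1, Sesn3, lower adjusted over the list alone, median −0.13) and of Wnt pathway feedback and receptors (19 tested, 0 by either adjustment, median −0.28) had camera adjusted p = 0.0179 and 0.0125, and 0.709 for both with an estimated correlation. Without Setd2 null 1, camera no longer called the lists of proliferation (adjusted p = 0.0908), Polycomb-repressed genes (0.249), AMPK and FOXO genes (0.62) or Wnt genes (0.249). The AMPK and Wnt calls were also lost without control 2 (camera adjusted p = 0.125 for both) and the MHC class I call without Setd2 null 2 (0.5), while the interferon list stayed called without any single library.

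The comparison of Ezh2 null with control asks what loss of the PRC2 methyltransferase does while Setd2 is intact. The lactoferrin gene Ltf rose from 7.36 ± 0.395 to 1047 ± 7.68 RPKM (SD, n = 2; log2 fold change 6.97 ± 0.158 SE, limma adjusted p = 6.02e-09). Crisp1, a secreted cysteine-rich protein gene, was listed at 0 in both control libraries and at 429.3 and 289.5 RPKM in the Ezh2 null libraries. Cdo1 rose from 0.716 ± 0.348 to 237 ± 24 RPKM and Abcb5 from 0.288 ± 0.0468 to 68.1 ± 5.83 RPKM. Mmp9, which encodes a matrix protease, fell from 320 ± 65.4 to 0.271 ± 0.0984 RPKM (log2 fold change −7.97 ± 0.293 SE, limma adjusted p = 2.18e-07), Tnc from 313 ± 4.12 to 3.39 ± 0.111 RPKM and Fn1 from 635 ± 10.8 to 15.8 ± 1.96 RPKM. Also lower were the claudin gene Cldn6 (48.3 ± 7.06 to 0.167 ± 0.0365 RPKM) and the activin gene Inhba (49.6 ± 3.7 to 1.12 ± 0.31 RPKM).

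Limma called 6416 of 11338 genes, 4096 higher and 2320 lower (63.8% higher), and 6997 at an unadjusted p under 0.05. At least 2-fold, 1368 rose and 845 fell. The median over all genes was 0.18, and quantile normalization, which moves it to 0.01, gave 3177 higher and 3158 lower genes (50.1% higher) and leaves the direction of small changes to the scaling.

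Genes of prostate epithelial identity were among those that changed. In the luminal prostate epithelium list 11 of 19 tested genes rose and 1 fell, over all genes and adjusted over the list alone, with Sbp (log2 fold change 5.73) and Cldn10 (3.22) among the former (median 0.85, camera adjusted p = 0.0103, and 0.258 with an estimated correlation). In the basal prostate epithelium list 6 of 17 rose, including Aqp3 (4.69), and 8 fell, including Lamb3 (−3.04) and Krt17 (−2.24), by either adjustment (median −0.34, camera adjusted p = 0.132). Androgen response genes went both ways, with 14 of 24 higher and 7 lower (8 adjusted over the list alone), such as Azgp1 (2.72) and Pmepa1 (−3.75; median 0.49, camera adjusted p = 0.32). Of 9 seminal vesicle and urothelial genes 7 rose and 2 fell by either adjustment, including Pate4 (5.11) and Krt13 (3.68; median 1.78, camera adjusted p = 0.0733). Epithelial junction genes were 9 higher and 6 lower of 25 by either adjustment, with Marveld3 at 1.29 and Epcam at −1.81, a median of 0.14 and a mean of −0.01, and camera's direction was negative (adjusted p = 0.678). Of the neuroendocrine list 2 genes were tested, of which Uchl1 fell (−1.97), and both were lower adjusted over the list alone (median −1.25, camera adjusted p = 0.132).

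Most of the interferon, inflammatory and matrix genes tested fell. Of 29 interferon response genes 27 fell and none rose (28 lower adjusted over the list alone), such as Ifi44 (log2 fold change −4.09) and Usp18 (−3.04; median −1.59, camera adjusted p = 1.21e-14, and 0.358 with an estimated correlation). MHC class I presentation had 7 of 18 lower (6 adjusted over the list alone, 11 after quantile normalization) and 0 higher, including Psmb8 (−1.35; median −0.53, camera adjusted p = 0.00189, and 0.603 with an estimated correlation). Of 26 inflammatory cytokine and acute phase genes 19 fell, such as Cxcl3 (−4.42) and Il1a (−3.94), and 3 rose, such as Saa3 (4.58), by either adjustment (median −1.34, camera adjusted p = 5.57e-08, and 0.0749 with an estimated correlation). Extracellular matrix and adhesion receptor genes had 27 of 34 lower and 3 higher by either adjustment, such as Lama3 (−4.11) and Itga2 (−3.67; median −1.27, camera adjusted p = 1.85e-11, and 0.156 with an estimated correlation). Of 18 mesenchymal transition genes 13 fell, such as Vim (−3.98), and 2 rose by either adjustment (median −1.85, camera adjusted p = 1.14e-06, and 0.0749 with an estimated correlation).

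Most proliferation genes tested rose and most glycolytic genes fell. Of 29 proliferation genes 23 rose and none fell by either adjustment, such as Mcm2 (log2 fold change 2.11) and Plk1 (1.48; median 1.07, camera adjusted p = 8.82e-06, and 0.494 with an estimated correlation). Glycolysis had 15 of 20 lower, such as Slc16a3 (−2.58) and Pfkp (−2.18), and 1 higher (2 adjusted over the list alone; median −0.69, camera adjusted p = 9.67e-06, and 0.494 with an estimated correlation). Sterol and fatty acid synthesis had 12 of 26 higher, such as Insig1 (1.21), and 3 lower by either adjustment (median 0.36, camera adjusted p = 0.598). AMPK and FOXO genes had 11 of 21 higher, such as Camkk2 (1.61), and 3 lower by either adjustment (8 and 4 after quantile normalization; median 0.38, camera adjusted p = 0.298). PI3K-AKT pathway genes had 8 of 22 higher, such as Pik3r3 (2.30), and 7 lower by either adjustment, and their median of 0.09 became −0.07 after quantile normalization (camera direction negative, adjusted p = 0.732). The 4 replication-dependent histone genes included 2 that rose by either adjustment, Hist1h2bc (1.88) and Hist1h1c (1.13; median 1.504, camera adjusted p = 0.207).

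Among chromatin and developmental genes, 13 of 26 Hox cluster genes rose and 9 fell by either adjustment, with Hoxb8 (log2 fold change 3.76) and Hoxb2 (3.06) the most significant (median 0.54, camera adjusted p = 0.598). Of 23 Polycomb-repressed genes 8 rose, such as Tbx2 (4.37) and Pax2 (2.84), and 4 fell, such as Timp3 (−1.71), by either adjustment, and the median of 0.06 became −0.09 after quantile normalization (mean 0.30, camera direction negative, adjusted p = 0.934). PRC2 subunit genes had 6 of 12 lower, including Ezh1 (−0.70) and Mtf2 (−0.78), and 2 higher (3 adjusted over the list alone), including Phf19 (0.99; median −0.29, camera adjusted p = 0.321). Of 15 other H3K36 and H3K27 methyl enzymes 2 rose, Smyd2 (1.13) and Kdm2b (0.78), and 4 fell by either adjustment (median −0.21, camera adjusted p = 0.197). The Y-linked member Uty fell from 6.61 ± 0.453 to 2.76 ± 0.589 RPKM. Wnt genes had 7 of 19 higher, such as Sp5 (3.61), and 8 lower, such as Wnt11 (−2.16), by either adjustment (median −0.20, camera adjusted p = 0.321). Imprinted genes had 3 of 9 higher, such as Grb10 (2.14), and 1 lower, Nnat (−1.26), by either adjustment, and their median of 0.18 became −0.02 after quantile normalization (camera adjusted p = 0.678). Immediate early and heat shock genes, a measure of handling, had 5 of 20 higher, such as Jund (1.56), and 3 lower by either adjustment (median 0.08, and −0.05 after quantile normalization; camera direction negative, adjusted p = 0.787).

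Markers of other cell types were also measured. Of 5 stromal genes 4 rose by either adjustment, Col3a1 from 0.104 ± 0.0296 to 6.64 ± 1.14 RPKM and Dcn from 1.18 ± 0.17 to 15.7 ± 4.39 RPKM among them, and Postn fell from 7.5 ± 1.23 to 0.217 ± 0.0078 RPKM (median 2.63, camera adjusted p = 0.132). Of 3 immune genes 1 rose by either adjustment, Lyz2, listed at 0 in control and at 7.69 and 8.20 RPKM in Ezh2 null, and 1 fell, Cd68 (log2 fold change −2.18; list median 0.01, mean 0.33 and −0.10 after quantile normalization, camera direction negative, adjusted p = 0.866). Of 2 endothelial genes 1, Esam, rose by either adjustment (1.21; median 0.55, camera adjusted p = 0.732).

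**Figure D3:**
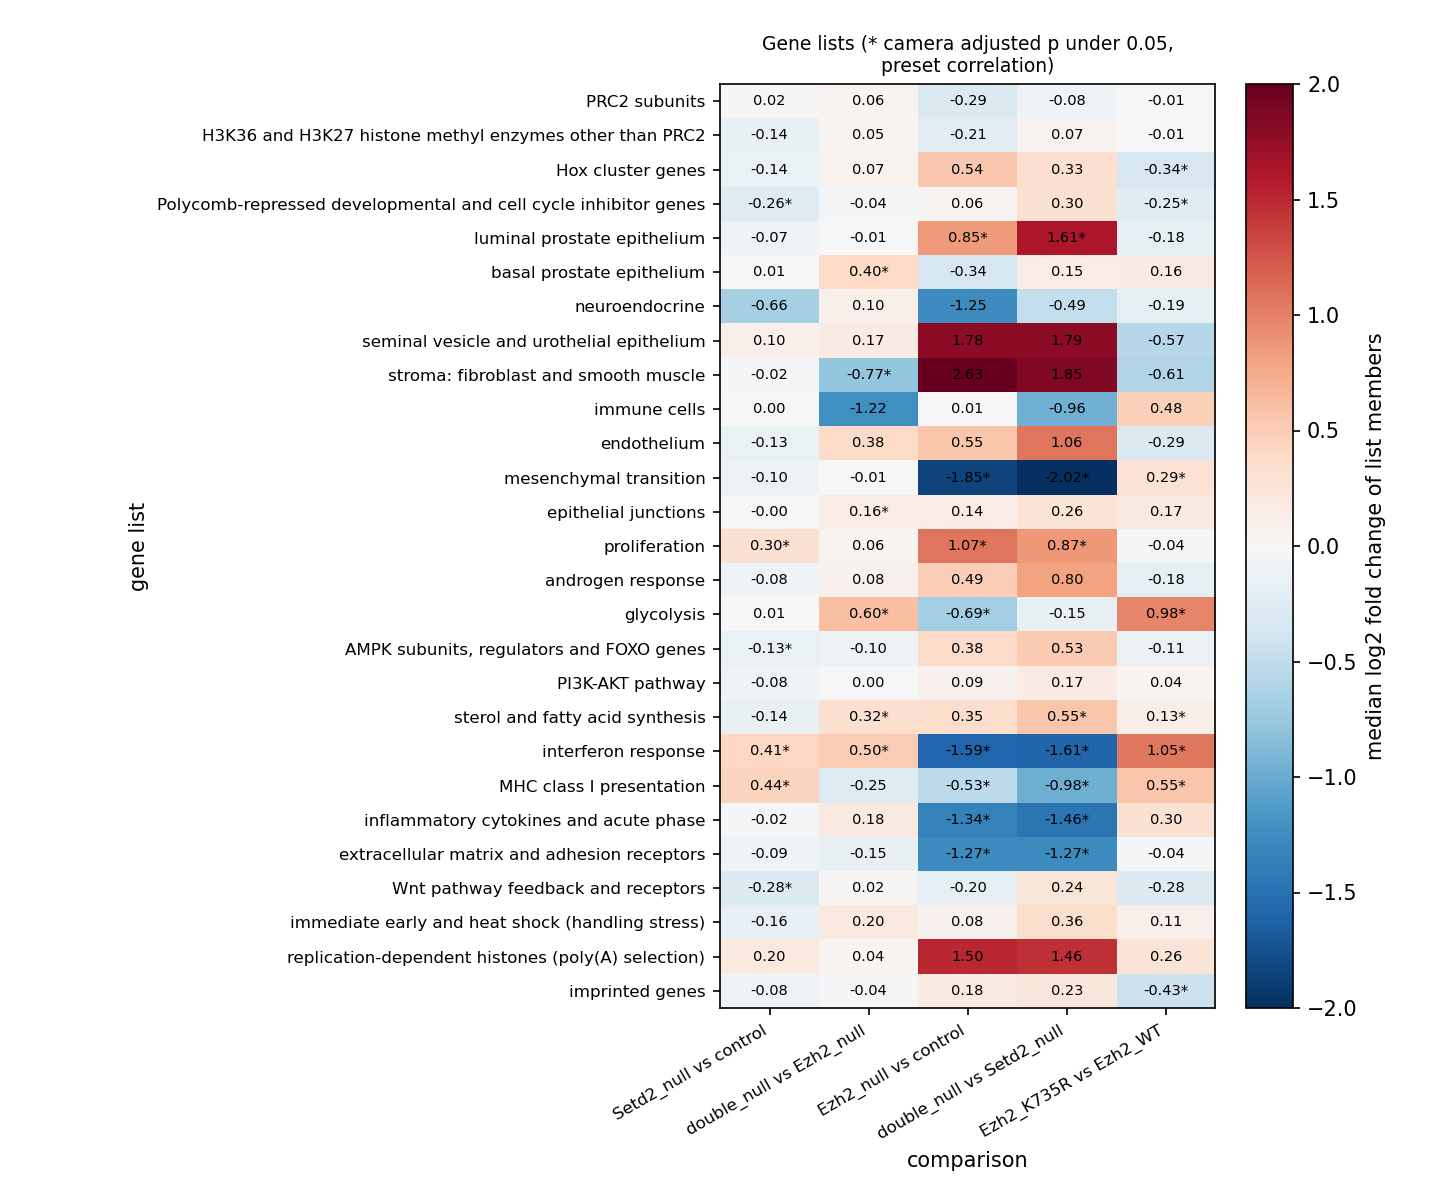
Median log2 fold change of the tested members of each fixed gene list (rows) in 5 comparisons (columns), with an asterisk at camera adjusted p under 0.05 with the preset correlation. The colour scale saturates at 2 in either direction, and the stromal median of 2.63 in Ezh2 null against control lies beyond it; small medians against control, such as 0.06 for the Polycomb-repressed genes, changed sign after quantile normalization.

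The comparison of double null with Setd2 null measures the effect of Ezh2 loss where Setd2 is also deleted. Krt10 rose from 0.817 ± 0.106 to 98.0 ± 19.7 RPKM (SD, n = 2; log2 fold change 5.75 ± 0.191 SE, limma adjusted p = 3.41e-08) and Aqp3 from 2.23 ± 0.216 to 167 ± 25.6 RPKM. Crisp1 was listed at 0 in both Setd2 null libraries and at 621.6 and 436.0 RPKM in double null. Mmp9 fell from 212 ± 102 to 0.199 ± 0.0218 RPKM, Mmp13 from 68.6 ± 0.476 to 0.0595 ± 0.00961 RPKM, Fn1 from 424 ± 178 to 6.66 ± 0.37 RPKM and Vcam1 from 84.1 ± 7.28 to 2.18 ± 0.132 RPKM. Limma called 6241 of 11338 genes, 4036 higher and 2205 lower (64.7% higher), and 6811 at an unadjusted p under 0.05. After quantile normalization, which moves the median of all genes from 0.18 to 0.00, the split was 2921 higher and 3122 lower (48.3% higher).

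The families called with Ezh2 loss alone were called again, apart from glycolysis, and sterol and fatty acid synthesis was added. Interferon response genes had 26 of 29 lower and 0 higher (27 lower adjusted over the list alone; median −1.61, camera adjusted p = 2.69e-14, and 0.383 with an estimated correlation), and MHC class I presentation had 14 of 18 lower and 1 higher (16 and 1 adjusted over the list alone), including B2m (log2 fold change −1.75; median −0.98, camera adjusted p = 3.03e-06, and 0.516 with an estimated correlation). Matrix and adhesion genes had 26 of 34 lower and 2 higher (26 and 3 adjusted over the list alone), inflammatory genes 19 of 26 lower and 3 higher and mesenchymal genes 12 of 18 lower and 4 higher, the last 2 lists by either adjustment. Their camera adjusted p were 8.94e-13, 1.35e-07 and 8.72e-06, and 0.13, 0.0928 and 0.102 with an estimated correlation. Proliferation had 24 of 29 higher and none lower, luminal genes 12 of 19 higher and 2 lower, and sterol and fatty acid synthesis 18 of 26 higher and 1 lower, such as Mvk (1.90) and Dhcr7 (1.37), all by either adjustment. Their camera adjusted p were 0.000128, 0.00227 and 0.00878, and 0.54, 0.163 and 0.54 with an estimated correlation. Glycolysis had 4 of 20 lower and 2 higher (4 and 1 adjusted over the list alone, 10 and 1 after quantile normalization; median −0.15, camera adjusted p = 0.0965).

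Across 11338 genes the log2 fold changes of Ezh2 loss with and without Setd2, from comparisons that share no library, correlated at Pearson r = 0.914 and Spearman rho = 0.921, where genes are not independent replicates. The comparisons may still not be independent, since the deviations of same-numbered Ezh2 null and double null libraries correlated at 0.933. Anything else common to the libraries without Ezh2 would enter both comparisons and raise the correlation and the overlaps. Calls overlapped in 3477 genes higher in both, against 1460 for independent lists, and 1860 lower in both, against 451. Opposite calls were fewer than the 797 and 826 of independent lists: 6 genes were higher in Ezh2 null and lower in double null against Setd2 null, including Mmp7, Tmem176a and Tmem176b, and 24 went the other way, including Arg1 and Id1.

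The comparison of double null with Ezh2 null measures the effect of Setd2 loss where Ezh2 is already deleted. Rpl29 fell again, from 291 ± 18.7 to 16.3 ± 0.375 RPKM (SD, n = 2; log2 fold change −4.07 ± 0.168 SE, limma adjusted p = 2.29e-06), and the antimicrobial gene Defb6 fell from 185 ± 48.9 to 20.2 ± 6.41 RPKM. The sulfotransferase gene Sult5a1 rose from 0.418 ± 0.219 to 19.9 ± 1.05 RPKM (log2 fold change 3.89 ± 0.148 SE, limma adjusted p = 1.45e-06) and the trefoil factor gene Tff1 from 0.886 ± 0.21 to 12.3 ± 1.97 RPKM. Cd200 was at 2.95 ± 0.0894 and 2.9 ± 0.471 RPKM, a log2 difference of −0.02 ± 0.333 SE. Limma called 736 of 11338 genes, 430 higher and 306 lower, and 1779 at an unadjusted p under 0.05. At least 2-fold, 158 rose and 83 fell. Leaving out a library gave 412 calls without Ezh2 null 1, 472 without Ezh2 null 2, 438 without double null 1 and 361 without double null 2.

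Camera called the interferon, glycolysis, basal and sterol lists higher in this comparison with its preset correlation, while most of their members did not pass over all genes. Of 29 interferon response genes 7 rose (10 adjusted over the list alone) and none fell, such as Oasl1 (log2 fold change 1.47) and Usp18 (1.08; median 0.50, camera adjusted p = 1.21e-10). Glycolysis had 6 of 20 higher (17 adjusted over the list alone) and 0 lower, such as Slc16a3 (1.32), Aldoc (1.20) and Pfkp (1.16; median 0.60, camera adjusted p = 6.38e-12). Basal genes had 7 of 17 higher (10 adjusted over the list alone) and 0 lower, such as Aqp3 (1.46), and sterol and fatty acid synthesis had 2 of 26 higher (3 adjusted over the list alone) and 0 lower. Their medians were 0.40 and 0.32, with camera adjusted p = 9.23e-09 and 8.31e-05. With an estimated correlation camera gave these 4 lists an adjusted p of 0.49. Of 26 Hox cluster genes 10 fell and 1 rose (12 and 9 adjusted over the list alone), such as Hoxb8 (−1.28) and Hoxb6 (−1.10), and the list's median was 0.08 while its mean was −0.21 (camera direction negative, adjusted p = 0.156). The immune genes Lyz2 (7.94 ± 0.357 to 2.84 ± 0.249 RPKM) and Cd14 (log2 fold change −1.39) fell while Cd68 rose (1.18), and the stromal gene Col3a1 fell from 6.64 ± 1.14 to 2.98 ± 0.141 RPKM. Camera called the stromal list lower (5 tested, 2 lower, with 1 higher and 3 lower adjusted over the list alone; median −0.77, adjusted p = 0.0332, and 0.49 with an estimated correlation), which was lost without double null 1 (0.0524) and turned positive at a mean of at least 5 RPKM (0.53, camera adjusted p = 0.215). It called the junction list higher (4 of 25 by either adjustment, such as Ovol1 at 0.92; median 0.16, adjusted p = 0.0122, and 0.633 with an estimated correlation), which was lost without Ezh2 null 1 (0.21) or double null 2 (0.276).

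Across 11338 genes the effects of Setd2 loss with and without Ezh2 correlated at r = 0.229 and rho = 0.306, where genes are not independent replicates. Of the 43 genes that rose on Setd2 loss in the presence of Ezh2, 34 (79.1%) had a positive log2 fold change in its absence, with a median of 0.39 (camera p = 9.38e-14, and 0.00247 with an estimated correlation). That median fell to 0.13 without control 1 and rose to 0.60 without Setd2 null 2. It was 0.65 for genes chosen at an absolute log2 fold change of at least 1. The 43 genes were chosen in the other comparison, with no libraries in common. Among the 78 genes that fell, the share that was also lower in the absence of Ezh2 was 53.8% (42 genes), with a median of −0.03 (camera p = 0.304, and 0.395 with an estimated correlation). Called in both comparisons were 17 higher genes, against 1.63 for independent lists, including Car12, Ivl, Klk8, Oasl1 and Rsad2, and 19 lower genes, against 2.11, including Rpl29, Hp, Wfdc18 and Glb1. Another 10 fell in Setd2 null and rose in double null, against 2.96, including Xlr3b and Id1, and 0 went the other way, against 1.16.

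The difference between the effects of Setd2 loss with and without Ezh2 was tested as an interaction. Limma called 294 of 11338 genes, 192 positive and 102 negative, and 1166 at an unadjusted p under 0.05. Leaving out control 1, control 2 or double null 2 left 157, 142 and 189 calls, and with the replicate number as a block limma called 469. Pfkp (interaction 1.19, limma adjusted p = 0.00428) had a positive difference, and Timp1 (−1.79, 0.00203) and Hoxb8 (−1.31, 0.00376) negative ones. Glycolysis had 3 of 20 genes called positive (4 adjusted over the list alone) and all 20 above 0 (median 0.55, camera adjusted p = 4.08e-11), basal genes 2 of 17 (4 adjusted over the list alone; median 0.49, camera adjusted p = 5.11e-07) and sterol and fatty acid synthesis 1 of 26 (3 adjusted over the list alone; median 0.29, camera adjusted p = 4.87e-06), each 0.356 with an estimated correlation. MHC class I presentation had 2 of 18 called negative and 1 positive (3 and 1 adjusted over the list alone; median −0.65, camera adjusted p = 9.78e-06), and immediate early and heat shock genes 0 of 20 by either adjustment (median 0.29, camera adjusted p = 0.00189), each 0.436 with an estimated correlation. The interferon list, called higher by camera on Setd2 loss in both settings, showed no called difference between them (median 0.15, camera adjusted p = 0.112). Its calls rest on the preset correlation, since with an estimated one camera gave it adjusted p of 0.709 with Ezh2 and 0.49 without, and 2 and 7 of its 29 genes passed.

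Camera also called 7 lists in the interaction whose calls ended when 1 library was left out. These were proliferation (median −0.21, adjusted p = 0.00317), lost without Setd2 null 1 (0.638); stroma (−0.78, 0.0218), lost without Setd2 null 2 (0.155); androgen response (0.22, 0.0218), lost without Setd2 null 2 (0.0736) or double null 2 (0.0516); and luminal epithelium (0.15, 0.0411), lost without Setd2 null 2 (0.351), Ezh2 null 1 (0.0986) or double null 2 (0.0516). The immune list (−0.97, camera adjusted p = 0.0411) was lost without Setd2 null 1 (0.053), Setd2 null 2 (0.155), Ezh2 null 2 (0.057) or double null 1 (0.064). The Polycomb-repressed list (0.23, camera adjusted p = 0.0417) was lost without control 2 (0.0687), Setd2 null 1 (0.7), Ezh2 null 1 (0.565) or double null 2 (0.466). The Wnt list (0.27, camera adjusted p = 0.0417) was lost without control 2 (0.157), Setd2 null 1 (0.361), Ezh2 null 1 (0.471) or double null 2 (0.373). With the replicate number as a block camera did not call the luminal (0.0601) or immune (0.0728) lists. At a mean of at least 5 RPKM it did not call the luminal (0.624), immune (0.665) or Polycomb-repressed (0.113) lists, and the stromal list turned positive (0.61, 0.176). With an estimated correlation camera gave these 7 lists adjusted p from 0.356 to 0.745.

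Double null against control combines both deletions. Aqp3 (1.35 ± 0.221 to 167 ± 25.6 RPKM; SD, n = 2) and Cdo1 (0.716 ± 0.348 to 130.1 ± 17.1 RPKM) rose, and Mmp9 (320 ± 65.4 to 0.199 ± 0.0218 RPKM), Fn1 (635 ± 10.8 to 6.66 ± 0.37 RPKM) and Tnc (313 ± 4.12 to 3.01 ± 0.03 RPKM) fell. Limma called 6147 of 11338 genes, 3874 higher and 2273 lower (63.0% higher), and 6761 at an unadjusted p under 0.05. After quantile normalization, which moves the median of all genes from 0.15 to −0.01, the split was 2937 higher and 3156 lower (48.2% higher). Camera called higher the lists of proliferation (25 of 29 genes higher, adjusted p = 8.96e-07) and luminal epithelium (12 of 19 higher and 3 lower, 0.00405). Called lower were interferon response (24 of 29 lower, 1.14e-10), MHC class I presentation (9 of 18 lower, 0.00022), inflammatory genes (20 of 26 lower and 4 higher, 6.73e-08), matrix and adhesion genes (28 of 34 lower and 2 higher, 1.71e-13) and mesenchymal genes (12 of 18 lower and 4 higher, 5.81e-06). Adjusted over the list alone, 26 proliferation genes were higher, 1 interferon gene higher and 24 lower, 5 inflammatory genes higher and 20 lower, and 29 matrix genes lower, with the other counts as given. With an estimated correlation camera's adjusted p for these 7 lists ranged from 0.086 for inflammatory genes to 0.552 for proliferation and MHC class I presentation.

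The comparison of K735R with wild-type Ezh2 asks whether the substitution changes expression as loss of Setd2 does. Rpl29 fell from 210 ± 20.7 to 23.5 ± 1.81 CPM (SD, n = 2; log2 fold change −3.17 ± 0.124 SE, edgeR adjusted p = 0.0288). It was the 1 gene that edgeR called of 13203, with 1220 at an unadjusted p under 0.05, 289 called by DESeq2, 2 by limma, and 4 by edgeR with the replicate number as a block. Without wild-type 1 edgeR called 644 genes and without wild-type 2 it called 1595, while without either K735R library it called 0 and lost Rpl29 (adjusted p = 1 and 0.563, with 1.67e-78 to 1 over the alternatives). Cd200, at 0.45 ± 0.355 CPM with wild-type Ezh2 and 57.5 ± 11.9 CPM with K735R, did not pass (log2 fold change 6.92 ± 0.497 SE, edgeR adjusted p = 0.187), nor did Fam162a (51.5 ± 6.29 and 136 ± 4.3 CPM; edgeR adjusted p = 0.187) or Kcnf1 (2.06 ± 0.51 and 18.1 ± 1.87 CPM; 0.189). EdgeR called all 3 without wild-type 1 (adjusted p = 7.05e-05 for Cd200, 0.000133 for Fam162a and 0.00028 for Kcnf1) or wild-type 2 (1.07e-05, 1.07e-05 and 0.000116), and none without either K735R library. DESeq2 also called all 3, and edgeR called Cd200 under the block. The 2 wild-type libraries differed from each other in matrix genes, with Fn1 at 86.5 and 1198 CPM and Tnc at 79.7 and 583.8 CPM. They correlated at r = 0.9686, and the 2 K735R libraries at 0.9854. Wild-type 2 correlated at 0.9705 and 0.9765 with the K735R libraries. Calls made without a wild-type library take their spread from the closer K735R pair alone, so they are not separate support.

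All 30 tested interferon response genes had positive log2 fold changes in K735R (median 1.05, camera adjusted p = 3.35e-12), and 0 passed by either adjustment. Glycolysis had 19 of 21 genes higher and 1 lower adjusted over the list alone and 0 over all genes (median 0.98, camera adjusted p = 1.13e-13), such as Ldha (719 ± 36.4 and 1436 ± 105 CPM) and Pfkp (25.6 ± 5.75 and 88.1 ± 19.6 CPM). MHC class I presentation was also called higher (19 tested, median 0.55, camera adjusted p = 6.83e-05), and Hox cluster genes (28 tested, median −0.34) and Polycomb-repressed genes (27 tested, median −0.25) lower, both at camera adjusted p = 0.000698, with 0 members passing by either adjustment. With an estimated correlation camera gave each of these lists an adjusted p of 0.642, and fry called 0 of 27. The calls on sterol and fatty acid synthesis (26 tested, median 0.13, camera adjusted p = 0.00947), mesenchymal transition (20 tested, 0.29, 0.0423) and imprinted genes (14 tested, −0.43, 0.0374), with 0 members passing by either adjustment and 0.642 with an estimated correlation, depended on single libraries. The sterol and imprinted calls were lost without wild-type 2 (camera adjusted p = 0.0643 and 0.127) or K735R 2 (0.0704 and 0.105), and the mesenchymal call without wild-type 1 (0.873) or K735R 2 (0.0956).

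Genes called on Setd2 loss moved the same way in K735R, as a set. Of 42 genes higher in Setd2 null that were tested in both, 37 (88.1%) had a positive log2 fold change in K735R. EdgeR called 0 of the 42, and their median was 1.10 (camera p = 1.31e-15, and 0.0454 with an estimated correlation). Of 77 lower genes 66 (85.7%) had a negative log2 fold change. EdgeR called 1 of the 77, Rpl29, and their median was −0.59 (camera p = 1.84e-10, and 0.0463 with an estimated correlation). The medians ranged from 0.56 under the replicate block to 1.41 without control 2 for the higher genes, and from −0.38 under the block to −1.08 without control 1 for the lower. Mmp13 was at 5.16 ± 4.49 CPM with wild-type Ezh2 and 32.2 ± 7.9 CPM with K735R. Across 11177 genes the log2 fold changes of Setd2 loss and of K735R correlated at r = 0.444 and rho = 0.413 (r = 0.302 without wild-type 2). Those of Ezh2 loss and of K735R correlated at r = −0.282 and rho = −0.256, and at 0.0504 without wild-type 1 and −0.4646 without wild-type 2. Genes are not independent replicates in either case.

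**Figure D4:**
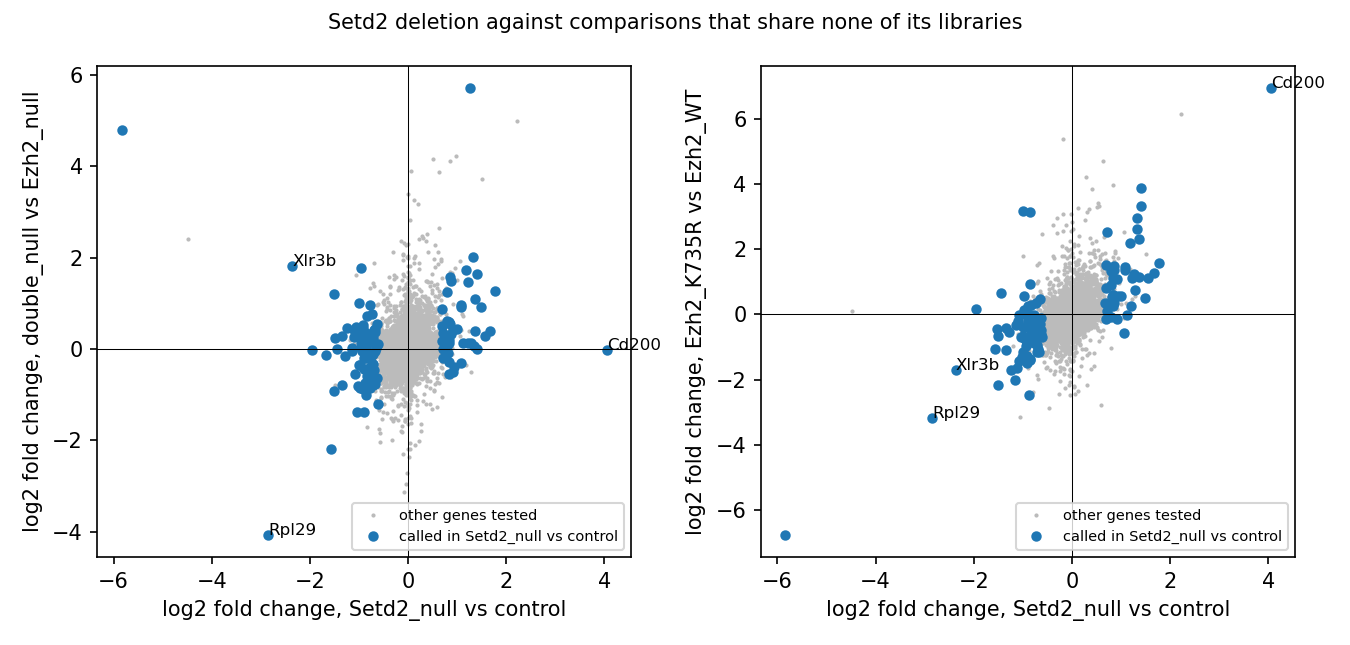
Log2 fold change of Setd2 null against control (x axes, on log2(RPKM + 1)) against that of double null over Ezh2 null (left, same scale) and of K735R over wild-type Ezh2 (right, edgeR log2 fold change of counts), with a point for each gene tested in both. Blue points are genes called in Setd2 null against control, all 121 on the left. On the right they are the 42 higher and 77 lower ones also tested in K735R. Cd200 lies at 4.05 and −0.02 in the left panel, and at 4.05 and 6.92 in the right.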

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

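The interaction test and the runs without single libraries were planned. The tests of the explanations weighed in this part were chosen after the result was seen, except the thinning to equal depth, whose outcome was set out beforehand although the alternative was added after the data were seen.

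The effect of Setd2 loss differed with and without Ezh2 in 294 genes by limma's interaction test. Positive differences among the genes named by the fixed rule included 4.18 for Xlr3b, 3.83 for Sult5a1, 3.39 for Sbpl and 3.25 for Sprr2d. The largest negative ones were −4.08 for Cd200, −3.06 for Defb6, −2.9 for Cryba4, −2.7 for Glb1l3 and −2.23 for Sftpd. Sbpl, Defb6, Cryba4 and Glb1l3 were near or at 0 in control and Setd2 null, and edgeR on recovered reads did not call their differences (adjusted p = 1, 0.914, 1 and 0.996, with lowest values of 1.48e-05, 0.000161, 8.18e-05 and 0.000102 over the alternatives). For Cd200 edgeR gave an adjusted p of 0.0549, and limma lost the call without Ezh2 null 1 (0.0743), Ezh2 null 2 (0.065) or double null 2 (0.0611), within a range of 0.000153 to 0.0743. Limma lost Sprr2d without Setd2 null 1 (0.0657), Setd2 null 2 (0.0871), Ezh2 null 1 (0.199), Ezh2 null 2 (0.119), double null 1 (0.199) or double null 2 (0.252).

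Some of the strongest changes in Setd2 null did not recur where Ezh2 was also deleted. Of Xlr3b and Cd200, 0 moved the same way in double null against Ezh2 null. Both were picked after their values were seen, so this restates the observation and decides nothing about other genes. Rpl29 fell in both settings (log2 fold change −2.85 with Ezh2 and −4.07 without). Called in both settings were 17 higher and 19 lower genes, against 1.63 and 2.11 for independent lists. For Xlr3b and Cd200 an effect of Setd2 loss that needs Ezh2 stays open as untested. Genes within 10 Mb of Setd2 were called more often than others (6 of 156 near, 121 of 11337 in all; Fisher's exact odds ratio 3.85, 95% interval 1.36 to 8.83, two-sided p = 0.00647), so alleles of another strain carried along near Setd2 are a candidate explanation for genes such as Glb1, Nme6, Pccb, Rpl29 and Sema3b, and leave the other called genes unexplained. Rpl29 was also low in K735R, where the labels name no Setd2 deletion. Moving reads between Rpl29 and its pseudogene Gm8210 is excluded as the whole cause in double null. The log2 ratio of the sum of both genes' reads against Ezh2 null was −2.96. Gm8210 rose from 0 and 0.043 CPM in Ezh2 null to 34.8 and 41.7 CPM in double null, where Rpl29 was at 29.7 and 30.3 CPM. Reads moved to Gm8210 could thus be part of the fall, and Gm8210 was among the 17 genes called higher in both settings. Other near-identical copies of Rpl29 were not tested, so reads assigned to those are not excluded.

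The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were lower in the libraries without Ezh2, at 59.6% and 45.6% of control in Ezh2 null and 75.6% and 58.1% in double null (median per library). Scaling of the libraries is excluded, since their median change lay below that of all genes by about 1 on the log2 scale, −0.97 after quantile normalization and −0.95 without it. A share of cells without a Y chromosome would lower the 4 genes alike, and they differed by up to 1.22 in log2 ratio within a library. It cannot be told apart from regulation of the single genes, since both could act together.

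The number of genes called between Ezh2 null and control was weighed against depth and other cells. After thinning every library to 29692426 reads edgeR called 7399 genes, against 7496 on all recovered reads, which excludes depth as the cause. The highest RPKM of the abundant stromal collagens Col1a1, Col1a2 and Col3a1 in Ezh2 null was 7.44. That argues against stromal cells as a sizeable part of the Ezh2 null cultures. Of 5 stromal genes tested 4 rose and 1 fell, so a small share of stromal cells stays open. No label gives a batch. The deviations of same-numbered Ezh2 null and double null libraries correlated at 0.933, against at most 0.358 for the other pairs of groups. A culture or library step shared by the libraries without Ezh2 was not tested. It cannot be told apart from Ezh2 loss in this design. An effect of Ezh2 loss stays open as the biological explanation.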

How the results depend on the processing

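The edgeR runs on recovered reads and the thinning were alternatives added after the data were seen, the thinning with its outcome set out before it was run. Apart from the values below, the main counts and correlations stayed within 1.5 times their value and the sets on their side of the threshold under each alternative run. Among all other results, such as single genes and lists, 10327 comparisons with an alternative gave the same call. These include changes of direction with no call in either run. Another 446 lost a call, 306 gained a call and 7 changed direction with a call in either run.

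With 121 genes called between Setd2 null and control, quantile normalization gave 56, no filter 67, a mean of at least 5 RPKM 62, only the groups compared 15, and an absolute log2 fold change of at least 1 gave 43. For double null against Ezh2 null (736), the mean of at least 5 RPKM gave 465, only the groups compared 399 and the fold limit 241. That fold limit gave 2213 for Ezh2 null against control, 2069 for double null against Setd2 null and 2034 for double null against control. The interaction (294) had 146 calls at a mean of at least 5 RPKM. On recovered reads edgeR called 136, 7496, 7249, 751, 7173 and 225 genes in the 6 contrasts of the first 4 groups. For K735R (1), DESeq2 gave 289 and limma 2. The fold limit by its construction keeps fewer genes. The fit on only the groups compared has fewer samples, but it did not always call fewer genes. It gave 6814 against 6416 for Ezh2 null against control and 6731 against 6147 for double null against control. For double null against Setd2 null it gave 5770 against 6241. For that fit and for the others the cause was not tested.

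Leaving out each library in turn gave 24 to 132 genes for Setd2 null against control, 361 to 472 for double null against Ezh2 null, 142 to 278 for the interaction and 0 to 1595 for K735R. The correlation of Setd2 loss with K735R ranged from 0.302 to 0.4469 and that of Ezh2 loss with K735R from −0.4646 to 0.0504. The lists called ranged from 3 to 9 for Setd2 null against control and from 5 to 11 for K735R. These fits have fewer samples. Without a wild-type library the fit for K735R takes its spread from the K735R pair alone. Without a K735R library it takes its spread from the wild-type pair alone. Which feature of a library moved the results was not tested.

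With an estimated correlation camera called 0 lists in each contrast, against 6, 8, 8, 6, 7, 12 and 8. Fry, which asks whether a list moves one way and not whether it differs from other genes, called 1 for Setd2 null against control, 17 for Ezh2 null against control, 18 for double null against Setd2 null, 17 for double null against control, 1 for the interaction and 0 for K735R. At a mean of at least 5 RPKM camera called 11 lists for double null against control, and the cause was not tested.

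Changes of direction with a call in either run were few, and those with no call in either run were not counted. Without control 1, camera's direction for the genes lower in Setd2 null turned positive in double null against Ezh2 null (p by camera with its preset correlation 0.681; median −0.003011), and it was called in neither run. The immune list in Ezh2 null against control was negative by camera and positive by fry (median 0.01, fry adjusted p = 0.00476), which compares with no other genes. At a mean of at least 5 RPKM the stromal list turned positive in double null against Ezh2 null (0.532, camera adjusted p = 0.215) and in the interaction (0.6082, 0.176), as fewer of its genes were tested. Without wild-type 2 the proliferation list in K735R became lower (−0.59, camera adjusted p = 1.63e-07; 0.92 without wild-type 1) and the matrix list higher (0.32, 0.0038; −0.235 without wild-type 1). Under edgeR on recovered reads the interaction of Glb1l3 became 0.36 (adjusted p = 0.996) and that of Mmp13 0.58 (adjusted p = 0.96), both near 0 in several groups. For these genes and the K735R lists the cause was not tested.

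The replicate numbers were used as a block, although no label says that the same number pairs libraries. The pairing check, the correlation of the deviations of same-numbered libraries, gave 0.933 for Ezh2 null with double null, 0.358 for control with Setd2 null, 0.155 and 0.133 for control with Ezh2 null and double null, 0.134 and 0.105 for Setd2 null with them, and 0.101 for wild-type with K735R. With the block, limma called 231 genes for Setd2 null against control, 7453 for Ezh2 null against control, 7232 for double null against Setd2 null, 1078 for double null against Ezh2 null, 7168 for double null against control and 469 for the interaction, and edgeR 4 for K735R. Under the block the 4 correlations were 0.2294, 0.9138, 0.4408 and −0.2935, and the medians in K735R of the genes called for Setd2 deletion were 0.5649 for the higher and −0.3831 for the lower genes. The block ended camera's interaction calls on the luminal (adjusted p = 0.0601) and immune (0.0728) lists, and raised the lists called from 6 to 8 for double null against Ezh2 null and from 7 to 8 for double null against control.

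With 2 libraries per group most changes of 1.5-fold went unrecovered in the simulations, at 11.9% for Setd2 null against control and 7.5% for K735R.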

Other observations

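Both tests in this part were chosen only after the result was seen.

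Crisp1, Defb6 and Wfdc15b, among the 10 genes that the fixed rule named for the highest log2 fold changes in Ezh2 null against control, were at or near 0 in control. Defb6 went from 0.102 ± 0.000303 to 185 ± 48.9 RPKM (SD, n = 2) and Wfdc15b from 0.67 ± 0.16 to 77.7 ± 1.1 RPKM. Pate4 was at 39.3 and 29.5 RPKM in Ezh2 null and 49.3 and 33.4 RPKM in double null, and at 0.0323 RPKM or below in the other 4 libraries. A hypothesis was that these genes come from cells of neighbouring ducts that entered the cultures. Of 19 epididymal genes, 2 (Adam28 and Aqp9) were above 1 RPKM in all 4 libraries without Ezh2 and above every other library, while Lcn5, Rnase9, Crisp4 and Spag11a were listed at 0 in all 8. Gpx5 was at 7.1 and 5.83 RPKM in Ezh2 null and 0.723 and 0.542 RPKM in double null. Cells of the seminal vesicle would bring its most abundant transcripts. The highest RPKM of Svs2, Svs4 and Svs5 in Ezh2 null was 8.54 (Svs4), and Svs1, Svs3a and Svs6 were listed at 0. By the rule used for the epididymal genes, 2 of 8 seminal vesicle genes passed, Svs4 and the higher Pate4. Svs2, Svs4 and Svs5, and the epididymal genes Adam7, Cst11 and Gpx5, were at 0 in every control and Setd2 null library. All of these were above 0 in every library without Ezh2. The 2 of 19 epididymal genes and the 8.54 RPKM of Svs4 argue against epididymal or seminal vesicle cells as a sizeable part of the cultures. A small share of such cells stays open, and expression of these genes in prostate cells without Ezh2 was not tested further.

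The first 83 genes of the count table stand in a separately sorted block ahead of the others. Of 82 tested, 63 had a negative log2 fold change in K735R (median −0.23), against 51.8% of the other genes. In Setd2 null against control 65 of 66 tested were negative (median −0.5), against 53.2% of the others, and limma called 8 lower. In Ezh2 null against control 61 of 66 were positive, and in double null against Setd2 null 66 of 66. How the block was chosen is not given in the sources used here, and a list picked on these samples is not independent evidence.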
